A study of Mus musculus with 4 samples.

How the data were processed

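RNA from the cerebral cortex of newborn mice (postnatal day 0) was measured on 4 Affymetrix gene arrays, 2 per genotype, and per the labels each array held RNA pooled from 3 cortices. The groups were taken from the labels: control mice with 1 floxed and 1 wild-type copy of Snf2h and an Emx1-Cre allele, and conditional knockout (cKO) littermates with 1 null and 1 floxed copy and the same Cre allele. Replicate numbers came from the sample titles. Whether the 2 pools of a genotype came from separate litters is not given in the sources used here, so p-values measure the spread between these pools, part of which may be technical.

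The deposited values are log2 signals, 1 per probe set and array, and the submitters' processing notes name RMA and Affymetrix Power Tools without versions. RMA corrects background, normalizes between arrays by quantiles and summarizes the probes of a probe set on the log2 scale. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed. The table held 35556 probe sets for each array, with values from 1.75 to 14.04. The array medians were 7.54 and 7.54 for the control arrays and 7.53 and 7.53 for the cKO arrays. No scanner files or detection calls were used here, so a low signal could not be separated from background by a detection test, and the number of arrays limits the precision.

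Gene symbols came from GEO's platform annotation. It named 1 gene for 21789 probe sets and several genes for 1621, and 12146 probe sets (34.2%) were unnamed there. Entrez identifiers of 21698 single-gene probe sets matched the RefSeq gene table of the GRCm38.p6 assembly, 91 did not, and the update changed 0 symbols. Only single-gene probe sets entered the gene tests. For the 999 genes with several such probe sets, the one with the highest mean over all 4 arrays was used, which left 19938 genes. No filter on low signal was applied in the main comparison.

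The comparison of cKO with control was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the deposited log2 values, with genotype as the sole term and all 4 arrays in the fit. All tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over the 19938 genes, with a threshold of 0.05. The prior added 4.33 degrees of freedom to the 2 residual ones. A second, descriptive count took genes with a fold change of at least 1.5 and an unadjusted p under 0.05. An exact permutation test of 2 arrays against 2 cannot give a p under 0.333, so none is reported for single genes.

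Gene lists and the rule for naming genes were fixed before the data were examined. The 32 lists covered ISWI and other chromatin remodellers, cohesin, protocadherins, cortical neuron classes, progenitors, cell cycle, p53 targets, synapse, axon guidance, other cell types that a dissected cortex can hold, stress responses and sex-linked genes. Shifts were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 29 lists. Camera was repeated with the correlation estimated from the residuals, and fry gave a self-contained directional test. The alpha and gamma protocadherin lists had no probe set naming a single member, so they were not tested and the union of the clusters equalled the beta list. The sex-linked genes are given gene by gene.

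Named genes were Smarca5 and its paralog Smarca1, 12 genes per direction, and up to 4 genes per list with the smallest p. The 12 per direction were those with the largest difference among genes with adjusted p under 0.05 and groups that did not overlap. Where fewer passed, the places were filled by smallest unadjusted p among non-overlapping genes with a fold change of at least 1.5, and such genes are stated not to have passed. Predicted genes and small RNAs were not named under that part of the rule.

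The scripts were tested on simulated data with the real genes and 2 arrays against 2. Over 20 simulated runs of 19938 genes, 67, 67 and 66 genes per run were changed by 0.5, 1 and 2 (log2). Of these limma recovered 46.9%, 96.6% and 99.8%, with a mean of 8.15 false calls per run. The adjusted threshold is easier to reach with that many changed genes than in the real data. There 3 genes passed, and Zfp975, at -1.38, did not (limma adjusted p = 0.446). The recovered shares thus do not show that changes of 1 or more are absent here. A simulated shift of -0.4 in the beta protocadherin list was called in 20 of 20 runs, and 0 of 560 tests of unshifted lists were called, with genes simulated as independent. The simulation therefore does not show how often camera calls unshifted lists when genes are correlated. In the real data, splits of the arrays that mix the genotypes called 10 and 6 lists, against 7 by genotype.

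The alternatives were each array left out in turn, the replicate number as a block, quantile normalization, median centring, removal of the lowest 25% or 50% of genes by mean signal, a trended and robust prior, all probe sets, the mean of a gene's probe sets, other thresholds and other set tests. Removal of X-linked and Y-linked genes and the other splits of the 4 arrays were added after the data were seen.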

Results

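The series profiled gene expression in the newborn mouse cortex after deletion of Snf2h, the ATPase of ISWI chromatin remodelling complexes, which is encoded by Smarca5. Emx1-Cre is active in the progenitors of the dorsal telencephalon, which give rise to cortical excitatory neurons and later to glia, but not in the lineages of interneurons, microglia, vessels or meninges. The control mice carried Emx1-Cre and kept 1 wild-type copy of the gene. By the labelled genotypes, cells outside the Cre lineage also differed. They held 1 null copy in cKO and 1 wild-type copy in control, each beside a floxed copy. Each genotype had 2 arrays (n = 2), and every array was a pool of 3 cortices labelled as male. Over 19938 genes, Pearson correlations between arrays, taken across genes, ranged from 0.995 to 0.9972. The SD of the log2 difference was 0.139 between the control arrays, 0.156 between the cKO arrays, and 0.148 to 0.190 between arrays of different genotype. The series title names Satb2, callosal projection neurons and clustered protocadherins, so the comparison asks which genes differ without Snf2h, among them those of neuronal identity and the protocadherin clusters.

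Smarca5 signal was lower in both cKO arrays, at 8.40 and 8.29, than in both control arrays, at 8.79 and 8.61. The means were 8.34 ± 0.075 in cKO and 8.70 ± 0.13 in control (log2, SD, n = 2), a difference of -0.36 (SE 0.087) or 0.778-fold, which did not pass limma's test over all genes (adjusted p = 0.582). Where the probes lie relative to the deleted part is not given in the sources used here, so this signal is a weak check of the genotype labels. Smarca1, the other ISWI ATPase, measured 9.14 ± 0.021 in cKO and 9.11 ± 0.077 in control, a difference of 0.02 (adjusted p = 0.965) whose sign turned without control replicate 2 (-0.03).

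Sex-linked genes separated the genotypes although all 4 arrays carried the same sex label. Uty, a Y-linked histone demethylase homologue, fell from 8.27 ± 0.086 in control to 4.28 ± 0.061 in cKO, a log2 difference of -3.99 (SE 0.077, adjusted p = 2.96e-05). Eif2s3y, a Y-linked translation initiation factor subunit, fell from 9.31 ± 0.34 to 4.41 ± 0.22 (difference -4.91, SE 0.17, adjusted p = 0.000649). Kdm5d, a Y-linked histone demethylase, fell from 8.73 ± 0.052 to 6.24 ± 0.18 (difference -2.50, SE 0.10, adjusted p = 0.000976). In the cKO arrays Uty and Eif2s3y lay between the 5.44 and 7.07 percentiles of all probe sets, so the size of their fold changes is limited by the low end of the scale. Xist, the RNA that coats the inactive X chromosome of female cells, was present in every array and measured 12.42 ± 0.0049 in cKO against 11.54 ± 0.10 in control, a difference of 0.88 that did not pass (adjusted p = 0.0908). The control arrays thus held both Y-linked and Xist signal, and the cKO arrays held Xist with Uty and Eif2s3y near the low end and Kdm5d at the 27.1 and 23.1 percentiles. Every difference between the genotypes given below was measured between arrays that also differed in this respect.

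**Figure D1:**
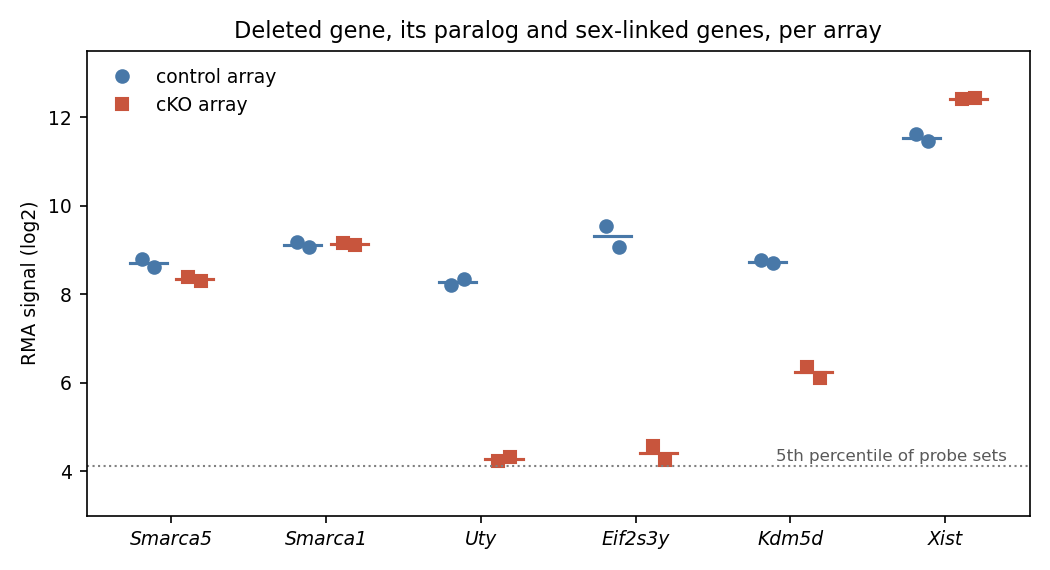
RMA signal (log2, vertical axis) of Smarca5, Smarca1, 3 Y-linked genes and Xist in the 2 control arrays (circles) and 2 cKO arrays (squares), with the group mean as a bar and the 5th percentile of all probe sets, averaged over arrays, as a dotted line. Uty and Eif2s3y have cKO means of 4.28 and 4.41, close to that line, while Smarca5 differs by -0.36.

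Across all genes, the 3 Y-linked genes were the only ones past an adjusted p of 0.05, all lower in cKO, and 0 genes were higher. At an unadjusted p under 0.05 there were 1397 genes, 793 higher and 604 lower in cKO. The descriptive limit of 1.5-fold with an unadjusted p under 0.05 took 40 genes, 17 higher and 23 lower. In all 40 both cKO arrays lay beyond both control arrays, which this limit nearly forces with 2 arrays per genotype. A split of the arrays by replicate number, which mixes the genotypes, took 45 genes at the same limit. Groups did not overlap for 37.7% of all genes, where chance gives 33.3%. With X-linked and Y-linked genes removed, an alternative added after the data were seen, 0 genes passed the adjusted threshold, 759 were higher and 583 lower at an unadjusted p under 0.05, and 36 met the descriptive limit. The descriptive count was 134 without cKO replicate 1 and 92 without control replicate 2.

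None of the 12 genes named as higher in cKO passed the adjusted threshold. After Xist, the smallest adjusted p belonged to Tac2, the neurokinin B precursor, at 8.05 ± 0.063 in cKO and 7.41 ± 0.058 in control (difference 0.64, SE 0.073, adjusted p = 0.256), and to Gfap, the intermediate filament of astrocytes, at 9.12 ± 0.070 and 8.28 ± 0.17 (difference 0.84, SE 0.097, adjusted p = 0.256). Chrna3, a nicotinic acetylcholine receptor subunit, differed by 0.90 (SE 0.21) and Met, the hepatocyte growth factor receptor, by 0.72 (SE 0.19), both with control arrays that lay far apart (SD 0.48 and 0.44). The others were the secreted protein gene Tafa1 (0.62), the olfactory receptor gene Olfr1029 (0.66), the membrane protein gene Emp1 (0.66), the transcription factor gene Dmrt2 (0.62), the lysozyme gene Lyz2 (0.61), the postsynaptic protein gene Ddn (0.62) and the Wnt agonist gene Rspo2 (0.59). Their adjusted p-values lay between 0.38 and 0.618. Olfr1029 lay in the lowest 25% of genes by mean signal, where a difference cannot be set against background without detection calls.

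Among the 12 genes named as lower, those beyond the 3 Y-linked ones did not pass either. Terc, the RNA template of telomerase, measured 8.91 ± 0.072 in cKO and 9.59 ± 0.0082 in control (difference -0.68, SE 0.071, adjusted p = 0.217). The zinc finger gene Zfp975 had the largest difference among them, -1.38 (SE 0.19, adjusted p = 0.446), and it was -1.69 with an adjusted p of 0.0187 without cKO replicate 2 (adjusted p from 0.0138 to 0.851 over its alternatives). Zfp931 differed by -1.01 and Zfp677 by -0.63. Psg16, of the pregnancy-specific glycoproteins, differed by -0.71, the glutathione transferase gene Gstm6 by -0.64, and S100a10, whose product binds annexin A2, by -0.60. The protocadherin genes Pcdhb21 and Pcdhb20 differed by -0.70 and -0.60. Several of these genes belong to families of similar paralogs, whose probes can share signal, so the identity of the single member is uncertain. Zfp975, Zfp931, Zfp677, Psg16 and Gstm6 also lay in the lowest 25% of genes by mean signal. Without detection calls, their differences cannot be set against background.

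The beta protocadherins, cell adhesion proteins encoded by a tandem gene cluster and expressed in different combinations by single neurons, were lower in cKO as a group. Of 22 members, all measured, 21 were lower and Pcdhb1 was higher by 0.04, with a median log2 difference of -0.42 and a range from -0.74 (Pcdhb19) to 0.04. Camera called the list lower (adjusted p = 1.08e-23), but the call was lost with an estimated correlation (adjusted p = 0.744 with an estimated correlation) and with fry (adjusted p = 0.767). Over all genes, 0 members passed limma's adjusted threshold and 20 were lower at an unadjusted p under 0.05. Adjusted over the list alone, 20 were lower. The series title names clustered protocadherins, so the list was chosen with this study in view and that count is not independent evidence of its direction.

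Pcdhb18 measured 7.76 ± 0.23 in cKO and 8.39 ± 0.016 in control (difference -0.64, SE 0.11), and Pcdhb17 measured 6.97 ± 0.23 and 7.64 ± 0.10 (difference -0.67, SE 0.12). Pcdhb21 (7.66 ± 0.19 in control, 6.97 ± 0.13 in cKO) and Pcdhb20 (8.27 ± 0.062 and 7.67 ± 0.17) are also among the 12 lower genes above. In 21 of the 22 members both cKO arrays lay beyond both control arrays, where chance gives 33.3% and all genes together showed 37.7%. The members are not independent of each other, so this count does not measure how unlikely the shift is. The median deviation of the list from each gene's mean was 0.201 and 0.196 in the control arrays, -0.351 in cKO replicate 1 and -0.0995 in cKO replicate 2, so the cKO arrays differed in the size of the shift. The list median was -0.30 without cKO replicate 1 and -0.55 without cKO replicate 2, and camera with the preset correlation called it in both. Beta isoforms are similar in sequence, and values of single isoforms are uncertain for that reason.

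The alpha cluster was represented by 1 probe set naming 14 alpha genes. It measured 8.63 ± 0.10 in cKO and 8.64 ± 0.10 in control, a difference of -0.01 with a 95% interval from -0.26 to 0.24 (adjusted p = 0.992 over all probe sets). This probe set names all alpha isoforms together, so a change in single isoforms could be hidden in it. The gamma cluster is not analysed here. The 17 non-clustered protocadherins had a median difference of 0.04 (camera adjusted p = 0.778), with Pcdh18 at 0.28, Dchs1 at -0.20, Fat3 at -0.17 and Pcdh8 at 0.10.

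**Figure D2:**
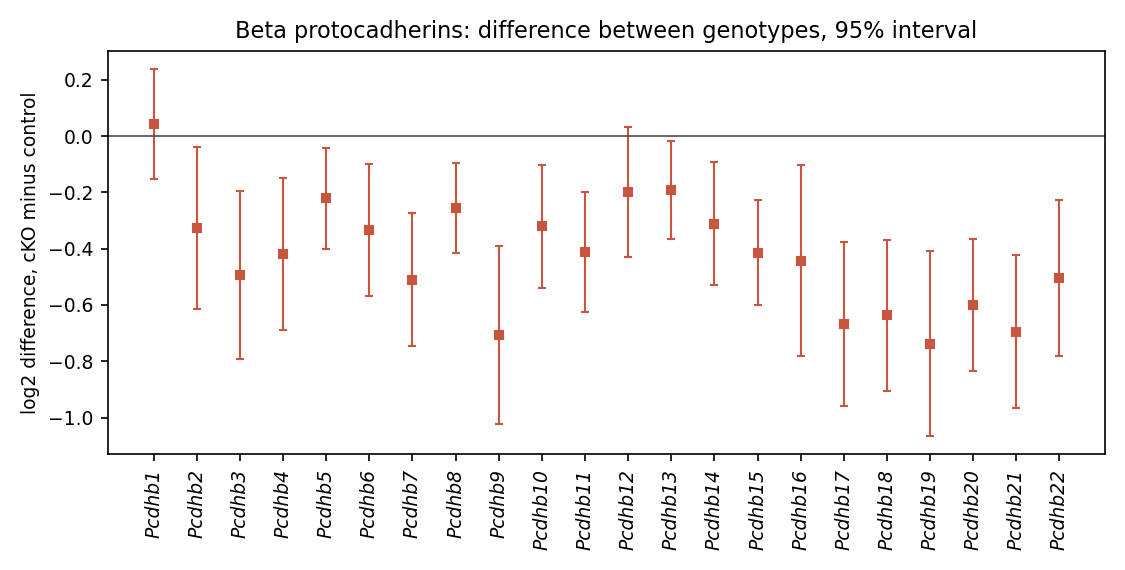
Log2 difference between cKO and control (vertical axis, cKO minus control) for the 22 beta protocadherin genes in order of their number, as squares with 95% intervals from limma and n = 2 arrays per genotype. The values run from -0.74 for Pcdhb19 to 0.04 for Pcdhb1, the sole member above 0.

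Astrocyte, microglia and meningeal fibroblast genes were higher in cKO as lists, and the size of these shifts depended on single arrays. Of 18 measured microglia and macrophage genes, 17 were higher, with a median of 0.24 (camera adjusted p = 9.43e-06, and adjusted p = 0.744 with an estimated correlation). Lyz2 passed adjusted over the list alone, and Fcer1g (0.25), Tyrobp (0.26) and C1qb (0.35), an Fc receptor chain, a signalling adaptor and a complement component, did not. Of 14 measured astrocyte genes, 12 were higher, with a median of 0.22 (camera adjusted p = 7.62e-05, and adjusted p = 0.744 with an estimated correlation). Gfap, the lipid carrier gene Apoe (0.39) and the glutamate transporter gene Slc1a2 (0.45) passed adjusted over the list alone, and the bicarbonate transporter gene Slc4a4 (0.39) did not. All 15 meningeal fibroblast genes were higher, with a median of 0.31 (camera adjusted p = 0.000322, and adjusted p = 0.744 with an estimated correlation), and 0 passed adjusted over the list alone. They included the retinoic acid synthesis gene Aldh1a2 (0.69, SE 0.26), the matrix genes Dcn (0.52, SE 0.30) and Ogn (0.57, SE 0.33), and the collagen gene Col1a2 (0.31, SE 0.14). The meningeal list deviated by -0.33 and -0.011 in the control arrays, -0.148 in cKO replicate 1 and 0.390 in cKO replicate 2. The astrocyte list deviated by -0.211 and 0.00461 in the control arrays, 0.0121 in cKO replicate 1 and 0.208 in cKO replicate 2. By replicate number, which mixes the genotypes, replicate 2 arrays were higher, by medians of 0.53 (meningeal), 0.17 (microglia) and 0.17 (astrocyte). Without cKO replicate 2 the medians were -0.0088 for meningeal genes (adjusted p = 0.926), 0.094 for microglia (adjusted p = 0.172) and 0.15 for astrocytes (adjusted p = 0.172), and 0 of these lists were called. The meningeal call was also lost without control replicate 1 (0.17, adjusted p = 0.08), where the astrocyte median was 0.069 and still called.

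Synaptic and neuronal maturation genes were higher as a list, with 16 of 20 measured members above 0 and a median of 0.10 (camera adjusted p = 0.00603, and adjusted p = 0.744 with an estimated correlation). The vesicular glutamate transporter gene Slc17a7 (9.73 ± 0.035 in control, 10.16 ± 0.15 in cKO, difference 0.43) passed adjusted over the list alone. Stx1a (0.23), Sv2b (0.28) and Nrgn (0.33), of synaptic vesicle release and postsynaptic calmodulin binding, did not, nor did the neurofilament gene Nefl, which was lower (-0.26). The call was lost without cKO replicate 2 (0.052, adjusted p = 0.428) and without control replicate 2 (0.083, adjusted p = 0.0589).

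Intermediate progenitor genes and cell cycle genes were lower as lists, with adjusted p-values next to the threshold. Of 12 intermediate progenitor genes, 9 were lower, with a median of -0.11 (camera adjusted p = 0.0497, and adjusted p = 0.744 with an estimated correlation). Eomes (Tbr2), the transcription factor that marks these cells, measured 9.11 ± 0.0025 in control and 8.33 ± 0.42 in cKO, a difference of -0.78 (SE 0.18). It fell less in cKO replicate 1 (8.62) than in cKO replicate 2 (8.03). Eomes and Neurod4 (-0.55) passed adjusted over the list alone, and Neurog1 (-0.18) and Sstr2 (-0.16) did not. Of 24 measured cell cycle genes, 14 were lower, with a median of -0.067 (camera adjusted p = 0.0497, and adjusted p = 0.744 with an estimated correlation), and 0 passed adjusted over the list alone. The cyclin gene Ccnb2 differed by -0.30, the mitotic kinesin gene Kif11 by -0.23, the ribonucleotide reductase gene Rrm2 by -0.20 and the replication licensing gene Cdc6 by -0.14. Without cKO replicate 2 the medians were 0.0017 (adjusted p = 0.379) and -0.019 (adjusted p = 0.172), and without control replicate 1 both calls were also lost (adjusted p = 0.226 and 0.0702). The cell cycle call was lost without each of the other arrays as well (adjusted p = 0.102 without control replicate 2 and 0.0692 without cKO replicate 1). The intermediate progenitor call was lost with the lowest 25% of genes removed (median -0.055, adjusted p = 0.123) and the lower 50% removed (adjusted p = 0.0586), the cell cycle call with median centring (adjusted p = 0.0511), and both with rank-based camera (adjusted p = 0.113 and 0.072) and with X-linked and Y-linked genes removed (adjusted p = 0.0503 for both).

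Lists of cortical neuron classes did not pass. Of 24 measured upper-layer and callosal neuron genes, 19 were lower, with a median of -0.04 (camera adjusted p = 0.233), and Satb2 is not analysed here. Lpl, the lipoprotein lipase gene, was higher by 0.40 and passed adjusted over the list alone, whereas Pou3f2 (-0.34), Plxnd1 (0.19) and Cux1 (-0.16) did not. Without control replicate 2 the upper-layer list was called lower (-0.097, adjusted p = 0.002), and without control replicate 1 its median was 0.0037. The 19 deep-layer projection neuron genes had a median of -0.03 (adjusted p = 0.223), with S100a10 (-0.60) past the threshold adjusted over the list alone and Tle4 (-0.24), Crym (0.31) and Igfbp4 (0.25) not. This list too was called without control replicate 2 (-0.070, adjusted p = 0.0189) and turned sign without control replicate 1 (0.037). Subplate genes (median 0.03, adjusted p = 0.444; Moxd1 0.34, Nxph4 -0.20, Lpar1 0.23, Svil 0.15) were not called. Nor were Cajal-Retzius genes (median 0.08, adjusted p = 0.177), among them Ndnf at 0.31, Nhlh2 at 0.15, Reln at 0.12 and Cdkn1c at -0.094. Hippocampal genes had a median of 0.05 (adjusted p = 0.443), with Neurod1 at 0.31, Nr3c2 at 0.33, Grik4 at -0.13 and Calb1 at 0.47. Without control replicate 1 these 3 medians turned to -0.044, -0.053 and -0.011, and without control replicate 2 the Cajal-Retzius list was called higher (0.17, adjusted p = 0.00973), as it was without cKO replicate 1 (0.14, adjusted p = 0.0451). Radial glia genes had a median of 0.025 (adjusted p = 0.325), with Slc1a3 at 0.19, Fgfr2 at 0.14, Hopx at 0.16 and Emx2 at 0.13. Axon guidance genes had a median of -0.03 but a mean of 0.0099 (adjusted p = 0.687), and their named members were Slit2 (0.43), Sema3a (0.23), Ephb1 (-0.14) and Slit3 (0.25).

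Markers of neurons from other regions or lineages were not called either. Interneuron genes had a median of 0.098 (adjusted p = 0.177), with Maf at 0.39, Npy at -0.39, Erbb4 at 0.32 and Lhx6 at 0.26, and the list was called higher without control replicate 2 (0.19, adjusted p = 9.45e-05) and was at -0.054 without control replicate 1. Striatal genes had a median of -0.047 (adjusted p = 0.177), with Meis2 at -0.13, Ikzf1 at -0.15, Rgs9 at -0.12 and Drd1 at -0.15, and the list was called lower without control replicate 1 (-0.087, adjusted p = 0.0205) and was at -0.0010 without control replicate 2. The 9 thalamic genes had a median of -0.17 (adjusted p = 0.789). Prkcd (0.34) passed adjusted over that list alone and Plekhg1 (0.27), Zic1 (-0.47) and Zic4 (-0.17) did not. Without control replicate 1 the thalamic list was called lower (-0.32, adjusted p = 0.000975) and without control replicate 2 higher (0.13, adjusted p = 0.0414).

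Of the non-neuronal lists, choroid plexus and ependymal genes had a median of 0.083 (adjusted p = 0.0979; Clic6 0.18, Kcnj13 0.32, Foxj1 0.11, Slc4a5 0.097). They were called higher without control replicate 2 (0.11, adjusted p = 0.0186) and without cKO replicate 1 (0.11, adjusted p = 0.0115), and had a median of 0.012 without cKO replicate 2. Oligodendrocyte lineage genes had a median of -0.027 (adjusted p = 0.444), with Gpr17 at -0.29, Olig2 at -0.18, Cspg4 at -0.16 and Bcas1 at 0.13. Endothelial and mural genes had a median of 0.019 (adjusted p = 0.654), with Mfsd2a at -0.22, Slco1a4 at 0.44, Cdh5 at 0.28 and Abcc9 at -0.14, and were called higher without cKO replicate 1 (0.12, adjusted p = 0.0161). The 7 measured erythroid genes had a median of 0.014 but a mean of -0.021 (adjusted p = 0.702), with Kel at -0.13, Hbb-bh1 at -0.17, Rhag at 0.093 and Alas2 at 0.045.

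Subunits of the ISWI complexes other than Smarca5 showed small differences. The 13 ISWI genes, which include Smarca5 as the lowest value (-0.36), had a median of 0.033 and a mean of 0.0040 (camera adjusted p = 0.789). Cecr2 was at -0.11, Rbbp4 at 0.10 and Pole3 at 0.081. Other remodeller subunits had a median of -0.0023 (adjusted p = 0.251), with Chd4 at -0.17, Smarcd3 at -0.16, Mta2 at -0.11 and Arid2 at -0.12, and the list was called lower without control replicate 2 (-0.030, adjusted p = 0.0395). CTCF and cohesin genes had a median of 0.037 (adjusted p = 0.444), with Smc3 at 0.073, Pds5a at 0.086, Pds5b at 0.082 and Stag1 at 0.070. The p53 targets had a median of 0.017 (adjusted p = 0.789), with the cyclin gene Ccng1 at 0.21, Eda2r at -0.16, Ano3 at 0.20 and Pidd1 at 0.19. Immediate-early genes, which respond to handling of tissue, had a median of 0.060 (adjusted p = 0.444; Junb 0.16, Atf3 0.18, Fosl2 0.12, Egr4 -0.10). Heat shock and unfolded protein response genes had a median of 0.045 (adjusted p = 0.443; Hspa5 0.35, Xbp1 0.21, Hspa1a 0.19, Atf4 -0.13). Interferon response genes had a median of -0.10 (adjusted p = 0.177; Ifit2 0.32, Usp18 -0.33, Stat2 0.25, Irf7 -0.28). They were called lower without control replicate 1 (-0.20, adjusted p = 0.000463) and had a median of -0.0040 without control replicate 2. Of the 29 lists tested, 7 were called with the preset correlation, and 0 with an estimated correlation or with fry, where 0 also had an unadjusted p under 0.05.

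**Figure D3:**
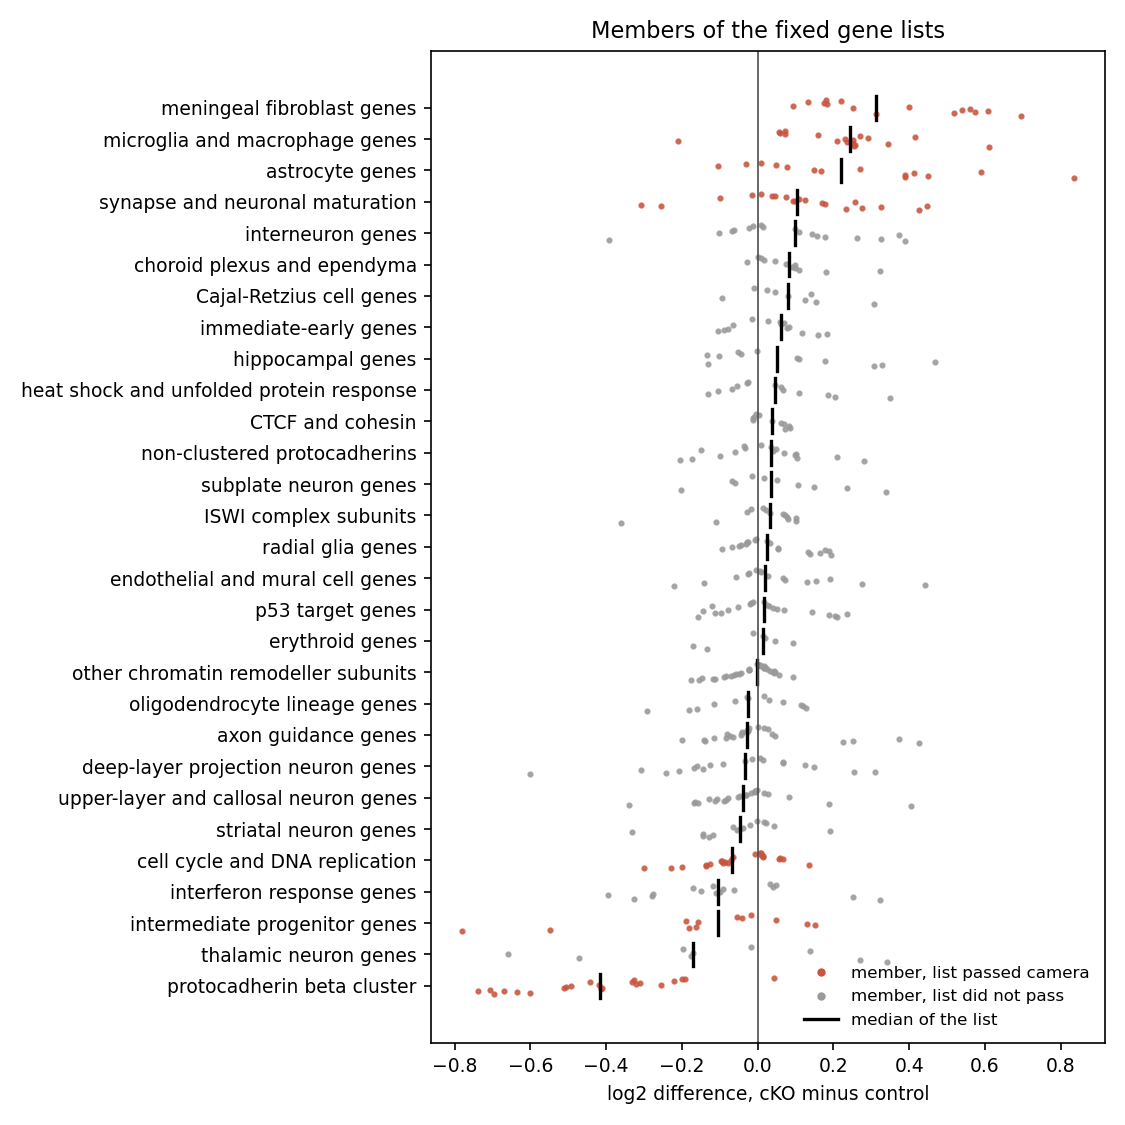
Log2 difference between cKO and control (horizontal axis, cKO minus control) of every measured member of the 29 tested lists, 1 dot per gene, with the list median as a black bar and red dots for the 7 lists that passed camera with the preset correlation. Medians run from -0.42 for beta protocadherins to 0.31 for meningeal fibroblast genes, and members of the same list spread to both sides of 0 in most lists.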

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

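Each alternative was run once with limma, and a single array left in a group was assumed to vary like the others. The count of 3 changed genes was 2 to 4 under each array left out, both normalizations, the lowest 25% of genes removed, the trended prior, all probe sets, the mean of a gene's probe sets, an adjusted p under 0.1 and a minimum fold of 1.1. It was 0 with the lower 50% of genes removed, where 0 of the 3 Y-linked genes were left and 805 genes had an unadjusted p under 0.05, and 0 with X-linked and Y-linked genes removed, which was added after the data were seen. Over all probe sets, the 2 that passed included the unnamed probe set 10608138, so most of the 3 Y-linked genes did not pass there. With the replicate number as a block the count was 31. Same-numbered arrays deviated together with r = 0.166 across genes, but there are just 2 pairs. The cKO mice were littermates of controls, yet nothing in the labels ties a replicate number to a litter or day, so the numbers were not taken to pair the arrays. Smarca5 stayed lower, by -0.27 to -0.45 with arrays left out, and its adjusted p lay between 0.129 (block) and 0.998. The descriptive count of 40 was 21 with the lower 50% removed, 233 over all probe sets, 5 at a fold of 2, and 46 to 134 with arrays left out.

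The beta protocadherin median was -0.30 to -0.55 with arrays left out. It was -0.42 with an estimated correlation (camera p = 0.0898, adjusted p = 0.744) and with fry (p = 0.062, adjusted p = 0.767). Both lost the call, and the cause was not tested. Both tests rest on 2 residual degrees of freedom, and 0 of the 29 lists had an unadjusted p under 0.05 in either. A call lost there therefore does not show that a shift is absent. The adjusted value of 0.744 is shared by many lists. The other lists called, 6 in the main comparison, were 0 with an estimated correlation, 0 with fry, and 0 (without cKO replicate 2) to 11 (without control replicate 2) with arrays left out. With X-linked and Y-linked genes removed 4 were called, and the intermediate progenitor and cell cycle calls were lost (adjusted p = 0.0503 for both). The intermediate progenitor call was also lost with the lowest 25% of genes removed (adjusted p = 0.123), the lower 50% removed (0.0586) and rank-based camera (0.113), and the cell cycle call with the replicate block (0.0656), median centring (0.0511) and rank-based camera (0.072). With the lower 50% removed, upper-layer genes (adjusted p = 0.0484), deep-layer genes (0.0402) and other remodellers (0.0398) were called lower.

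Medians that turned sign with arrays left out ranged as follows. Intermediate progenitor genes ranged from -0.19 to 0.0017 and meningeal genes from -0.0088 to 0.52. Other remodellers ranged from -0.030 to 0.00024, upper-layer genes from -0.097 to 0.0037 and deep-layer genes from -0.070 to 0.037. Subplate genes ranged from -0.044 to 0.12, Cajal-Retzius genes from -0.053 to 0.17 and hippocampal genes from -0.011 to 0.14. The p53 targets ranged from -0.023 to 0.028, axon guidance genes from -0.021 to 0.0089, interneuron genes from -0.054 to 0.19 and thalamic genes from -0.32 to 0.13. Oligodendrocyte genes ranged from -0.033 to 0.013, endothelial genes from -0.068 to 0.12, erythroid genes from -0.042 to 0.0077 and heat shock genes from -0.010 to 0.071. Median centring put other remodellers at 0.0067, and removal of the lower 50% put radial glia genes at -0.0033 and oligodendrocyte genes at 0.0011. Named genes that turned sign with arrays left out were Smarca1 (-0.033 to 0.077), Stag1 (-0.0026 to 0.14), Drd1 (-0.30 to 0.010) and Alas2 (-0.042 to 0.13). The cause of these turns, and of the moves in the counts other than by removal of Y-linked genes, was not tested. Of the 135 other named genes, 17 that had not passed did so with the replicate block, Xist also with the trended prior (adjusted p = 0.0107, and 0.00656 to 0.484 over its alternatives) and Zfp975 also without cKO replicate 2. All other tests of named genes kept their direction and side of the threshold in the alternatives where named genes were followed singly. All probe sets, the mean of a gene's probe sets, other thresholds and the removal of X-linked and Y-linked genes were not among these. Of the 135 genes, 122 were left with the lowest 25% of genes removed and 92 with the lower 50% removed. The rest were not tested there, among them Zfp975, Zfp931, Zfp677, Psg16, Gstm6 and Olfr1029 in both. Without detection calls, differences among genes of low signal cannot be set against background.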

Other observations

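The tests of the Zfp family, of the explanations weighed here and of the other splits of the arrays were chosen after the values they concern had been seen. Zinc finger genes named Zfp with a number, many of which encode DNA-binding repressors, tended to lower values in cKO. Of 317 measured, 49 were lower and 3 higher at an unadjusted p under 0.05, 0 passed adjusted over all genes with limma, and 5 were lower adjusted over the family alone. The median log2 difference was -0.063, and camera with the preset correlation put the family lower (p = 6.05e-09, but p = 0.152 with an estimated correlation). Without cKO replicate 2 the median was -0.0039, with the preset camera p at 0.000904. Zfp975 measured 5.45 ± 0.43 in cKO and 6.83 ± 0.084 in control (SD, n = 2), Zfp931 5.45 ± 0.058 and 6.46 ± 0.36, and Zfp599, picked after its values were seen, 8.46 ± 0.051 and 8.88 ± 0.021.

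A drift of dim probe sets was argued against for this family, since 10000 lists matched on mean signal had a typical median of 0.011 (permutation p = 1e-04, the smallest they can give, which takes genes as independent). The family median was smaller in size without dim genes. It was -0.047 with the lowest 25% of genes removed and -0.031 with the lower 50% removed, against -0.063 with all genes. A strain segment linked to Smarca5 was argued against as the source of most of the lower Zfp genes, since 8.16% of them lay on its chromosome and the rest on others. Such a segment stays open for the 4 genes on that chromosome, and strain segments elsewhere were not tested. A difference in sex composition between the pools cannot be told apart from genotype, because 0 pairs of a control and a cKO array had matching Uty signal (within 1 log2 unit). The 4 arrays have 3 splits, too few for a share under 0.05. The real split was 1 of 3 with as many as 49 Zfp genes one way, and the highest other split had 8.

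The second pattern was the Y-linked and Xist signal, which contradicts a sex label of male for every pool. Pools of mixed sex for control and of mainly or wholly female cortices for cKO are a candidate explanation, since Uty and Eif2s3y reached at most the 7.07 percentile in the cKO arrays while Xist lay above the 96th in all 4. Whether arrays were exchanged between the genotypes stays open, since the largest difference in Y-linked signal within a genotype (0.476) restates the pattern, and Smarca5, which ran as labelled without overlap (8.79 and 8.61 in control, 8.40 and 8.29 in cKO), did not pass its test and has probes of unknown position. The X-linked genes Kdm6a (0.40), Kdm5c (0.25), Eif2s3x (0.24) and Ddx3x (0.04), picked after their values were seen, differed by these log2 amounts and did not pass (adjusted p between 0.487 and 0.923). No biological explanation was tested, since the design names no sex difference.

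The third pattern was the lower beta protocadherin signal. A neuron loss in cKO large enough to lower neuronal genes as much as the beta list was argued against by the synapse list. Its median was 0.103 (0.052 and not called without cKO replicate 2), above the beta list by 0.52. The p for that gap (permutation of genes between the lists, 100000 resamples, p = 1e-05, the smallest they can give) takes genes as independent and came after both medians were seen. The list also covers neuronal maturation, so it does not measure neuron share alone. A smaller loss stays open, since upper-layer (-0.04, 19 of 24 lower) and deep-layer (-0.03, 11 of 19 lower) medians were slightly lower, though not called. Astrocyte (0.22), microglia (0.24) and meningeal (0.31) medians were higher, as a lower neuron share would also give. Sex composition cannot be told apart from genotype here either, with 0 pairs of arrays matched on Uty, and the loss of Snf2h stays among the open explanations. The 3 splits of the arrays are too few for a share under 0.05. The real median was -0.42, and the largest median of the other splits was 0.134 in size, so 1 of 3 splits, the real one, reached it, although camera with the preset correlation also gave p = 3.5e-05 for that other split, in which each side holds 1 array of each genotype.

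A split of the arrays by replicate number called 10 lists, more than the 7 of the real split, 3 of them also called there. Its medians were 0.53 for meningeal, 0.17 for microglia and 0.17 for astrocyte genes (replicate 2 arrays higher, against 0.31, 0.24 and 0.22 by genotype). It had 0 genes past the adjusted threshold, 916 unadjusted and 45 at the descriptive limit, against 3, 1397 and 40 by genotype. The remaining split called 6 lists, with 0 genes past the adjusted threshold, 510 unadjusted and 6 at the descriptive limit. Probe set 10608138, unnamed in the annotation used here, measured 8.38 ± 0.064 in control and 5.18 ± 0.024 in cKO (difference -3.20, adjusted p = 0.00821 over all probe sets).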
